A study of Homo sapiens with 6 samples.

How the data were processed

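HEK293 cells, an established human embryonic kidney cell line, had been made to carry APOL1 under a doxycycline-inducible (Tet-on) promoter, and the arrays here hold 3 groups named after the APOL1 genotype, G0, G1 and G2, all with doxycycline. G0 is the reference form of APOL1, and G1 and G2 are the coding variants linked to kidney disease risk. Each group has 2 arrays, numbered 1 and 3 in the sample titles. Uninduced cells, empty-vector cells and the Illumina arrays that the study's design mentions are not analysed here, so induction by doxycycline was not tested. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Genotype and cell line change together in this design, and the labels name no batch.

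The authors deposited log2 values from Affymetrix HTA 2.0 arrays, summarised per transcript cluster with RMA per the submitters' processing notes, and the RMA version and the set of arrays normalised together are not given in the sources used here. RMA subtracts background, gives all arrays the same distribution of probe values and combines the probes of a cluster by median polish. The table holds 67414 rows with values from 1.99 to 19.93. The highest value recurs as an exact maximum in 21 to 28 rows of each array, so it acts as a ceiling. Exact ties between arrays occurred in 0.881% of gene rows. The median log2 value per array lay between 4.69 and 4.74. The number of arrays, 2 per group, limits the precision.

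Rows were named through the platform's annotation table, with symbols updated through gene IDs against the RefSeq gene table of GRCh38.p14, which was used for names, gene class and gene span only. Of the rows, 23781 had 1 gene symbol, 1543 had several and 42090 had none. Of the rows with 1 symbol, 21497 matched by gene ID, 1974 matched by symbol and 310 stayed under the older symbol. Rows with several symbols or none were left out of the gene tests. Where a gene had more than 1 row (479 genes), the row with the highest mean over the 6 arrays was kept, which left 22465 genes, and 37 of these rows hold the same values as another gene's row. No filter on dim genes was applied.

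Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on all 6 arrays, with 3 residual degrees of freedom and 3.36 prior degrees of freedom. The 3 comparisons were G1 minus G0, G2 minus G0 and G2 minus G1, and a moderated F test compared the 3 groups. Unless stated otherwise, adjusted p-values are from limma with Benjamini-Hochberg adjustment over the genes tested in that comparison, at a threshold of 0.05. Errors of differences are standard errors (SE) of the fit, and errors of group values are SDs over 2 arrays. Gene lists (51, fixed before the data were examined, of which 50 had at least 5 measured members) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. The list of genes encoded in mitochondrial DNA had no named member on the array table and was not tested. The same lists were run with a correlation estimated from the data, a test that rests on 3 residual degrees of freedom, and with fry. Camera compares a list with the other genes, while fry asks whether the list's own genes changed. The overlap of the comparisons that share the G0 arrays was set beside 100 simulated data sets of unchanged genes and beside the overlap of independent lists.

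The genes named were chosen by a rule fixed before the data were examined. For each comparison these were the 8 largest rises and 8 largest falls past the threshold with no overlap between the arrays of the groups, up to 4 members of each list past the camera threshold (those with the largest moderated statistic in the list's direction), at most 2 members past the gene threshold from each other list, the 6 genes that rose and the 6 that fell most in both G1 and G2, and APOL1 to APOL6. Uncharacterised symbols (LOC, open reading frame, LINC, microRNA, snoRNA and other small RNA genes, pseudogenes and clone names) were passed over in the rules for the largest changes; 2 were passed over among the falls of G1 against G0 and 2 among the rises of G2 against G1. In this rule, genes changed in both G1 and G2 were ranked by the smaller of their changes. Genes named outside this rule are said to be so.

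The fit was tested on simulated data made from the means of the 22465 genes and the moderated spreads of the fit, with independent normal noise. In each comparison 67 genes were changed by 0.5 log2, 67 by 1 log2 and 66 by 2 log2. For G1 minus G0 it recovered 52.2% of changes of 0.5 log2, 98.5% of changes of 1 log2 and 100% of changes of 2 log2, with 11 false calls. For G2 minus G0 these were 53.7%, 97% and 100% with 17 false calls, and for G2 minus G1 56.7%, 97% and 100% with 13 false calls. Far fewer genes were changed here than passed between the real groups, so these shares need not carry over. In a simulation of 100 lists of genes drawn independently, camera called 10 of the 10 shifted by -0.3 log2 and 0 of the others. The correlations estimated for the real lists ran from -0.127 to 0.806. The simulation therefore does not show the error rate of camera for lists whose genes vary together. Alternatives covered a filter on dim genes, the prior variance, cyclic loess, centring on the median, only the 4 arrays of a comparison, the replicate number as a block, the mean of all rows of a gene, every row tested by itself, a fold threshold, and each array left out in turn. Others, chosen after seeing the data, left out gene rows with tied values and removed a trend of the changes with gene span and mean level.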

Results

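Gene expression was measured on 6 Affymetrix HTA 2.0 arrays of HEK293 cells made to carry APOL1 under a doxycycline-inducible promoter. APOL1 encodes apolipoprotein L1, a secreted and intracellular protein that can form ion channels. The groups were G0 (n = 2 arrays), G1 (n = 2) and G2 (n = 2), all with doxycycline. The study's title names mitochondrial dysfunction induced by the renal-risk variants as its subject. Across 22465 genes, the arrays of a group correlated at r = 0.997 to 0.998. The correlation between arrays was 0.981 to 0.989 for G0 with G1, 0.972 to 0.978 for G0 with G2 and 0.992 to 0.995 for G1 with G2. These correlations are across genes, which are not independent replicates.

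The APOL1 row did not separate the groups. Its log2 value was 8.03 on 5 of the 6 arrays, exactly tied, and 7.98 on G0 replicate 3. APOL1 differed from G0 by 0.03 ± 0.07 (SE) log2 in G1 (adjusted p = 0.839) and by 0.03 ± 0.07 in G2 (adjusted p = 0.823). APOL2, APOL3, APOL4, APOL5 and APOL6, the neighbouring members of the family, did not pass the threshold in any comparison. The largest of their differences was that of APOL5 between G2 and G1, -0.27 ± 0.08 log2 (adjusted p = 0.116). Tied values carry no spread, and whether the probes of this row detect the transgene was not established here, so the row cannot show whether the lines expressed APOL1 at the same level.

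**Figure D1:**
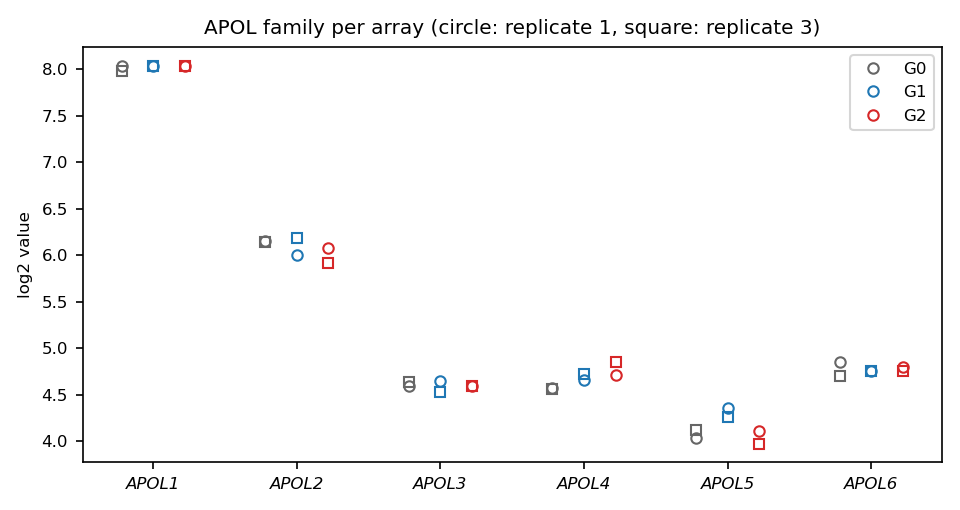
Deposited log2 value of APOL1 to APOL6 on each array (vertical axis), by gene (horizontal axis), with circles for replicate 1 and squares for replicate 3 and colours for the G0, G1 and G2 groups. APOL1 lies at 8.03 on 5 arrays and at 7.98 on 1, and no member of the family passed the threshold between groups.

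The comparison of G1 with G0 asks how cells with this risk variant differ from cells with the reference form. Of 47 genes of the integrated stress response, the program that the transcription factor ATF4 drives when translation initiation is restrained, 27 fell and 3 rose in G1 (camera adjusted p = 6.36e-10; adjusted p = 0.494 with an estimated correlation). SLC7A11, which encodes the cystine transporter, fell by 3.85 ± 0.39 (SE) log2 (adjusted p = 0.00154), from 12.98 ± 0.48 (SD, n = 2) in G0 to 9.13 ± 0.77 (SD, n = 2) in G1. CHAC1, a glutathione-degrading enzyme (-3.56 ± 0.28), CTH of the transsulfuration pathway (-3.16 ± 0.31) and DDIT3, the stress factor CHOP (-2.67 ± 0.19), fell as well. Of 39 immediate early genes, which respond first to growth factor and stress kinase signals, 34 rose and 0 fell (camera adjusted p = 1.42e-23; adjusted p = 0.246 with an estimated correlation). EGR1 rose by 4.06 ± 0.16 log2 (adjusted p = 0.000418), ZFP36 by 3.53 ± 0.16, DUSP1 by 3.17 ± 0.12 and NR4A2 by 2.89 ± 0.10. ANKRD1, a cardiac and muscle ankyrin-repeat protein, had the largest rise, 6.61 ± 0.29 log2 (adjusted p = 0.00047).

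The integrated stress response list had a median of -0.73 log2 (adjusted p = 0.494 with an estimated correlation), and DDIT4 (-2.83 ± 0.17), SESN2 (-2.55 ± 0.16) and STC2 (-1.86 ± 0.14) were among those that fell. Of 28 genes of the endoplasmic reticulum stress response, 10 fell and 0 rose (median -0.40, camera adjusted p = 0.00601; adjusted p = 0.678 with an estimated correlation). Among these, HERPUD1 (-2.62 ± 0.23) and the transcription factor gene XBP1 (-1.96 ± 0.21) fell. The immediate early list had a median of 0.90 log2 (adjusted p = 0.246 with an estimated correlation). As adjusted over the list alone, 38 integrated stress response genes fell and 3 rose, 10 endoplasmic reticulum stress genes fell and 0 rose, and 36 immediate early genes rose and 0 fell.

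Of 74 mitochondrial ribosome genes, 41 fell and 1 rose in G1 (median -0.36, camera adjusted p = 1.83e-09; adjusted p = 0.39 with an estimated correlation), among them MRPL15, which fell by 1.33 ± 0.11 log2, and MRPS10, which fell by 1.24 ± 0.11. Of 32 genes of complex I, 17 fell and 0 rose (median -0.34, camera adjusted p = 2.89e-05; adjusted p = 0.246 with an estimated correlation), with NDUFB5 falling by 0.89 ± 0.14. Of 17 ATP synthase genes, 8 fell and 0 rose (median -0.36, camera adjusted p = 4.44e-05; adjusted p = 0.39 with an estimated correlation). CYC1 of complex III fell by 1.18 ± 0.14 log2, and CPT2 (-1.77 ± 0.19) and ECH1 (-1.44 ± 0.14) of fatty acid oxidation fell. Of 29 proteasome genes, 20 fell and 0 rose (median -0.46, camera adjusted p = 4.29e-09; adjusted p = 0.351 with an estimated correlation), including PSMA3 (-1.45 ± 0.12) and PSMA6 (-1.37 ± 0.10). With p-values adjusted over the list alone, 46 genes of the mitochondrial ribosome fell and 1 rose, 21 of complex I fell and 2 rose, and 13 of ATP synthase and 21 of the proteasome fell and 0 rose. Among lists of nuclear genes for mitochondrial proteins in G1, those of mitochondrial DNA maintenance and transcription (camera adjusted p = 0.242), carriers (adjusted p = 0.273) and mitophagy (adjusted p = 0.475) did not pass.

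Extracellular matrix and inflammatory genes were higher in G1. Of 38 genes of the TGF-beta response and matrix, 18 rose and 0 fell (camera adjusted p = 4.93e-07; adjusted p = 0.246 with an estimated correlation), including CCN2, connective tissue growth factor (3.03 ± 0.22), TIMP3 (2.17 ± 0.19), TGFB2 (1.94 ± 0.09) and fibronectin, FN1 (1.56 ± 0.12). Of 32 NF-kappaB and inflammatory genes, 10 rose and 2 fell (camera adjusted p = 5.53e-05; adjusted p = 0.246 with an estimated correlation), with CCL2 at 2.17 ± 0.10 and NFKBIA at 1.96 ± 0.14. ATP1B1 and ATP1B3, beta subunits of the sodium-potassium pump, rose by 1.28 ± 0.09 and 1.25 ± 0.13 log2. Their list of potassium and sodium transport had 10 members that rose and 1 that fell of 37 (camera adjusted p = 0.00478; adjusted p = 0.246 with an estimated correlation). The linker histone gene H1-4 fell by 2.71 ± 0.22 log2, and 13 of 20 replication-dependent histone genes fell (camera adjusted p = 2.73e-05; adjusted p = 0.279 with an estimated correlation). IBTK, which encodes an inhibitor of Bruton tyrosine kinase, fell by 2.88 ± 0.31, while FNBP4 and ZFP36L2 rose by 2.92 ± 0.25 and 2.76 ± 0.22. When adjusted over the list alone, 20 TGF-beta and matrix genes rose and 0 fell, 13 inflammatory genes rose and 2 fell, 12 transport genes rose and 1 fell, and 14 histone genes fell and 1 rose.

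In all, 5481 genes passed limma's threshold between G1 and G0, of which 2446 were higher and 3035 lower, and 398 and 503 of these changed by at least 2-fold. Without G0 replicate 3 the number was 3350, and without G1 replicate 1 it was 3444. With camera, 27 of 50 lists passed (9 up, 18 down). With an estimated correlation 0 passed, and 10 had an unadjusted p under 0.05. Since 24.4% of all genes passed, the 34 lists called by fry, which sets no list against other genes, are no like count.

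The comparison of G2 with G0 asks the same of the other risk variant. SLC7A11 fell by 5.76 ± 0.39 log2 (adjusted p = 0.000229), to 7.22 ± 0.32 (SD, n = 2). PSAT1 of serine synthesis fell by 4.67 ± 0.37, from 15.62 ± 0.49 to 10.95 ± 0.07 (SD, n = 2 each). CHAC1 (-3.99 ± 0.28), CTH (-3.76 ± 0.31) and HSPA5, the chaperone BiP (-2.61 ± 0.29), also fell. ANKRD1 rose by 7.58 ± 0.29 log2 (adjusted p = 0.000167), CCN2 by 4.95 ± 0.22, EGR1 by 4.37 ± 0.16 and the protocadherin gene PCDH19 by 4.07 ± 0.08 (adjusted p = 2.9e-05).

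Of the 47 integrated stress response genes, 40 fell and 3 rose in G2 (median -1.43, camera adjusted p = 6.62e-13; adjusted p = 0.406 with an estimated correlation), including DDIT3 (-3.23 ± 0.19), DDIT4 (-3.05 ± 0.17) and AARS1 (-2.28 ± 0.14), an aminoacyl-tRNA synthetase. Of the 28 endoplasmic reticulum stress genes, 17 fell and 1 rose (median -0.75, camera adjusted p = 1.6e-05; adjusted p = 0.567 with an estimated correlation), with HERPUD1 at -3.03 ± 0.23 and XBP1 at -2.58 ± 0.21. Of the 39 immediate early genes, 35 rose and 0 fell (median 1.28, camera adjusted p = 1.38e-19; adjusted p = 0.328 with an estimated correlation). Adjusted over the list alone, 42 integrated stress response genes fell and 3 rose, 20 endoplasmic reticulum stress genes fell and 1 rose, and 36 immediate early genes rose and 0 fell.

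Among mitochondrial lists in G2, 55 of 74 mitochondrial ribosome genes fell and 3 rose (median -0.57, camera adjusted p = 1.48e-13; adjusted p = 0.343 with an estimated correlation). MRPL58, a peptidyl-tRNA hydrolase of the mitochondrial ribosome, fell by 2.68 ± 0.12 log2. Of 32 complex I genes, 25 fell and 2 rose (median -0.59, camera adjusted p = 5.18e-07; adjusted p = 0.291 with an estimated correlation), with NDUFA12 at -1.41 ± 0.13. Of 43 assembly factors of the respiratory complexes, 26 fell and 3 rose (median -0.68, camera adjusted p = 1.93e-07; adjusted p = 0.291 with an estimated correlation). Among these TACO1, a translational activator of COX1 (-2.76 ± 0.13), and TIMMDC1 (-2.28 ± 0.12) fell. Of 17 ATP synthase genes, 15 fell and 0 rose (median -0.58, camera adjusted p = 2.31e-06; adjusted p = 0.343 with an estimated correlation), including ATP5PD (-2.06 ± 0.15). Of 26 fatty acid oxidation genes, 14 fell and 2 rose (camera adjusted p = 0.000108; adjusted p = 0.368 with an estimated correlation), with CPT2 at -2.67 ± 0.19 and ACAA2 at -1.70 ± 0.14. Adjusted over the list alone, the genes that fell numbered 59 for the mitochondrial ribosome (3 rose), 25 for complex I (2 rose), 27 for assembly factors (3 rose), 15 for ATP synthase (0 rose) and 18 for fatty acid oxidation (2 rose). The lists of mitochondrial DNA maintenance and transcription (camera adjusted p = 0.284), carriers (adjusted p = 0.181) and mitophagy (adjusted p = 0.859) did not pass in G2.

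Proteasome genes were lower in G2, 21 of 29, with 1 higher (median -0.57, camera adjusted p = 1.54e-07; adjusted p = 0.343 with an estimated correlation), among them PSMD5 (-2.42 ± 0.18) and PSMB6 (-1.60 ± 0.11). Of 46 genes of the G2 and mitosis phases of the cell cycle, 25 fell and 7 rose (camera adjusted p = 0.000219; adjusted p = 0.557 with an estimated correlation), including HMMR (-1.82 ± 0.10) and KIF20A (-1.51 ± 0.10). Heat shock genes were higher, 11 of 20, with 1 lower (median 0.41, camera adjusted p = 0.000491; adjusted p = 0.462 with an estimated correlation), including HSPB8 (2.93 ± 0.13), DNAJA1 (1.66 ± 0.15) and DNAJB1 (1.40 ± 0.11). Of 38 matrix and TGF-beta genes, 23 rose and 1 fell (camera adjusted p = 7.62e-08; adjusted p = 0.291 with an estimated correlation), and of 32 NF-kappaB and inflammatory genes, 14 rose and 2 fell (camera adjusted p = 0.000193; adjusted p = 0.291 with an estimated correlation). The chemokine gene CXCL8 rose by 3.34 ± 0.23, TNFAIP3 by 2.01 ± 0.11 and NFKBIA by 2.61 ± 0.14. TNFRSF10D, a decoy receptor for the ligand TRAIL, rose by 3.62 ± 0.22 and the ephrin receptor gene EPHA2 by 3.51 ± 0.17, while MIF4GD (-3.58 ± 0.20) and VPS25 (-3.28 ± 0.17) fell. Adjusted over the list alone, 22 proteasome genes fell and 1 rose, 28 genes of G2 and mitosis fell and 7 rose, 11 heat shock genes rose and 1 fell, 24 matrix and TGF-beta genes rose and 1 fell, and 16 inflammatory genes rose and 2 fell.

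Between G2 and G0, 7443 genes passed limma's threshold, 3260 higher and 4183 lower, and 803 and 1059 of these changed by at least 2-fold. With camera, 27 of 50 lists passed (8 up, 19 down). With an estimated correlation 0 passed, and 7 had an unadjusted p under 0.05. The 37 lists called by fry are again no like count, as 33.13% of all genes passed.

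**Figure D2:**
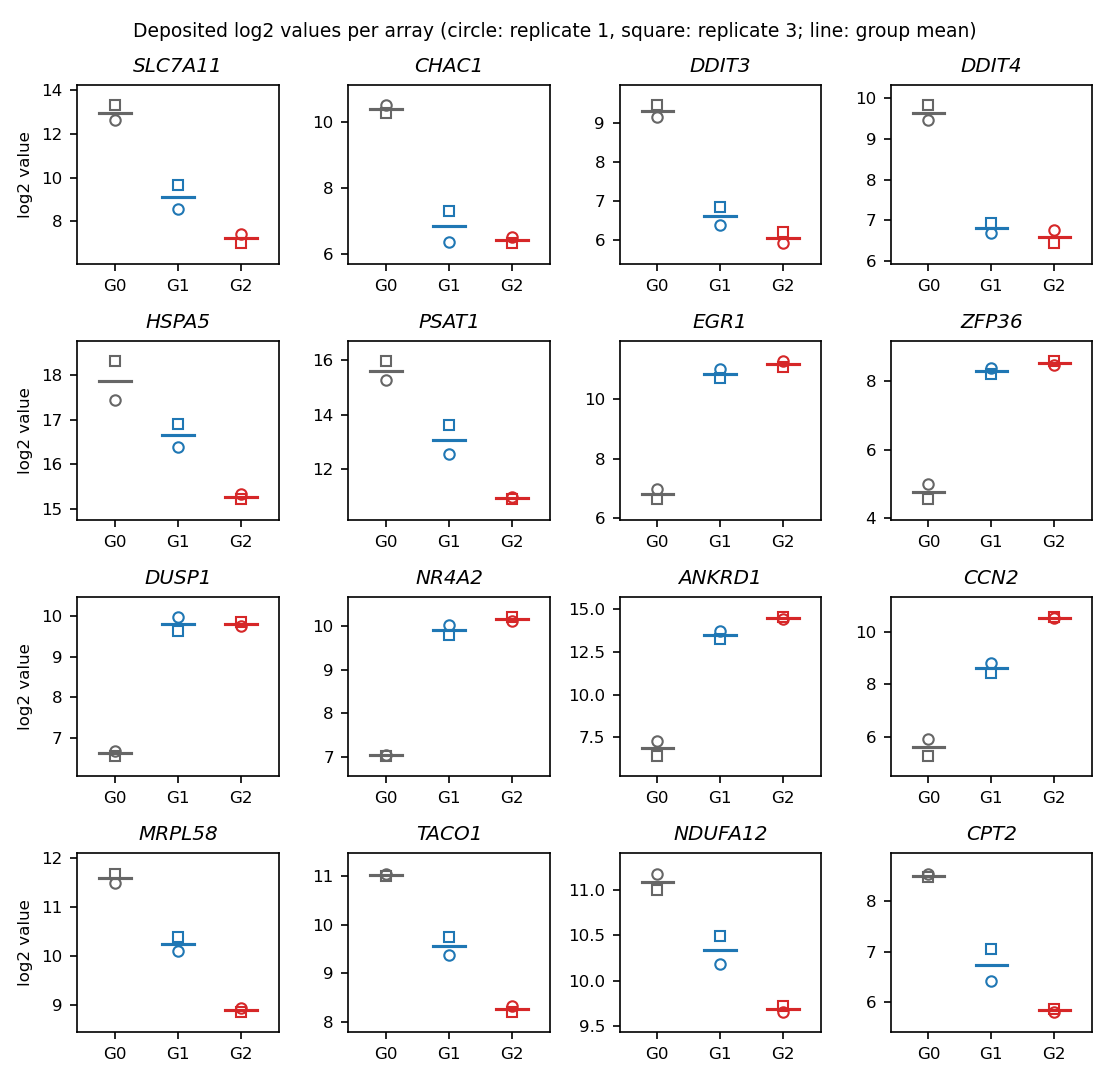
Deposited log2 values (vertical axes) of 16 genes on the arrays of each genotype group (horizontal axes), with circles for replicate 1, squares for replicate 3 and lines for group means. SLC7A11 is at 12.98 in G0, 9.13 in G1 and 7.22 in G2, and EGR1 at 6.80, 10.86 and 11.16.

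**Figure D3:**
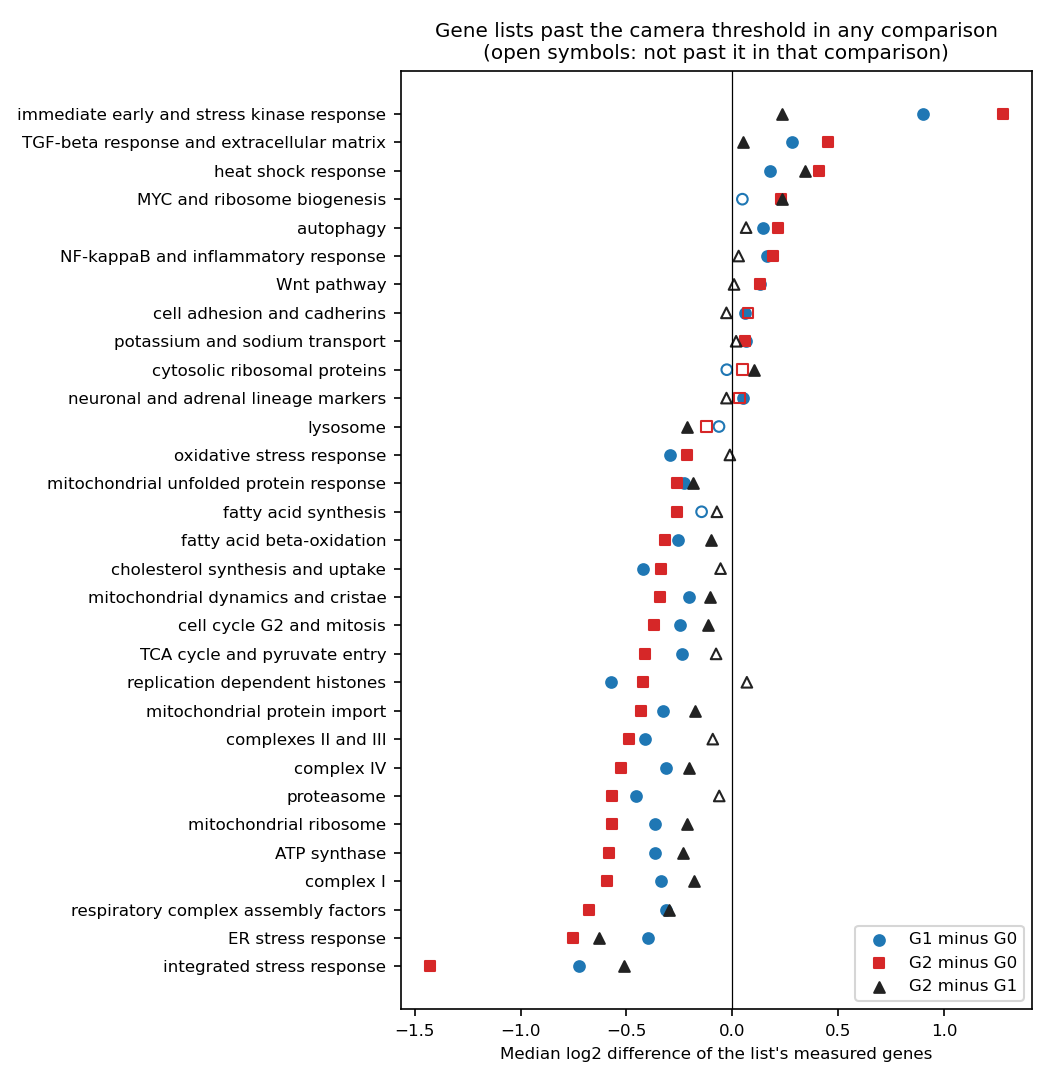
Median log2 difference of the measured genes (horizontal axis) for each list past the camera threshold in at least 1 comparison (vertical axis), with filled symbols where that comparison passed. The integrated stress response list lies at -0.73 for G1 minus G0 and -1.43 for G2 minus G0, and the immediate early list at 0.90 and 1.28.

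The comparisons with G0 were set side by side to ask which genes changed in both variants. Of the genes past the threshold in both comparisons, 2092 were higher and 2621 lower in both, and 19 went opposite ways. Characterised genes were ranked by the smaller of their changes in G1 and G2. By this rank, ANKRD1, EGR1, ZFP36, DUSP1, CCN2 and FNBP4 rose most in both, and SLC7A11, CHAC1, CTH, IBTK, DDIT4 and H1-4 fell most in both. Independent lists of these sizes would share 355 higher and 565 lower genes. In simulated data with no changed gene, both comparisons used the same simulated G0 arrays, and at most 1 gene was shared. Few genes can pass in such data, so this count cannot show the overlap that shared controls give alongside real changes. The fold changes correlated at r = 0.890 across genes against 0.498 in the simulation, with a covariance of 0.209 against 0.00618, and 78.3% of genes had the same sign against 66.65%. The G0 arrays were not split, since each part would hold 1 array, so part of the excess over independent lists may come from the shared controls. Of the genes changed in both, 78.4% had the larger change in G2. Over both directions 4713 genes changed the same way in both, 2938 without G0 replicate 3 and 3060 without G1 replicate 1.

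**Figure D4:**
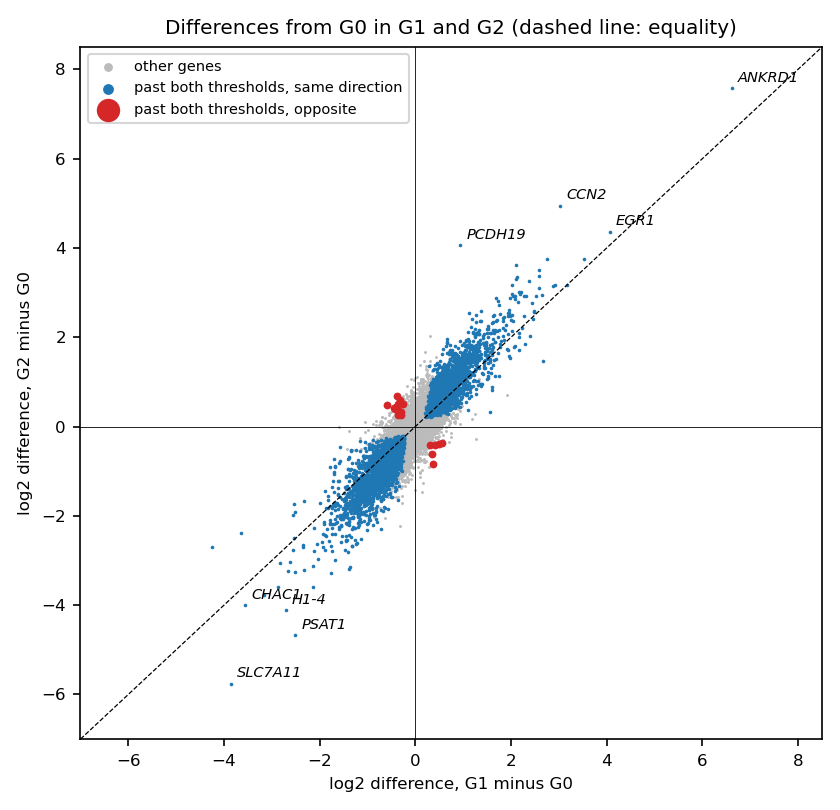
Log2 difference from G0 of each gene in G1 (horizontal axis) and G2 (vertical axis), with genes past both thresholds in the same direction in blue, in opposite directions in red and other genes in grey. The fold changes correlate at r = 0.890 across genes, and 19 genes lie in opposite quadrants.

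The F test across the 3 genotypes passed 7322 genes. In 5360 of these (73.2%) the G1 mean lay between those of G0 and G2. The G2 mean lay between the other two in 1399 and the G0 mean in 563.

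The comparison of G2 with G1 tests whether the G2 and G1 lines differ. Genotype and cell line change together, so it cannot separate the variants from the lines. PCDH19 rose by 3.14 ± 0.08 log2 in G2 over G1 (adjusted p = 0.000151), from 6.04 ± 0.05 to 9.18 ± 0.05 (SD, n = 2 each), and was the gene with the largest difference. CCN2 rose by 1.92 ± 0.22 (adjusted p = 0.0134), PTN, the growth factor pleiotrophin, by 1.73 ± 0.09, and TNFRSF10D by 1.51 ± 0.22. NSD3, MIDN, SP4 and the cyclin gene CCNE2 rose by 1.28 to 1.48. PSAT1 fell by 2.15 ± 0.37 (adjusted p = 0.0259), and SLC7A11 (-1.90 ± 0.39) and the amino acid transporter gene SLC7A5 (-1.80 ± 0.32) fell too. The other large falls were SLCO4C1 (-1.91 ± 0.25), SLFN11 (-1.79 ± 0.24), PDIA4 (-1.60 ± 0.32), TRAPPC1 (-1.59 ± 0.15) and the immunoglobulin segment IGHD2-8 (-1.56 ± 0.31).

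Of the integrated stress response genes, 14 were lower and 2 higher in G2 than in G1 (median -0.51, camera adjusted p = 1.13e-07; adjusted p = 0.609 with an estimated correlation). The mitochondrial ribosome had 16 lower and 0 higher (median -0.21, camera adjusted p = 4.65e-09; adjusted p = 0.609 with an estimated correlation), and the assembly factors had 14 lower and 2 higher (median -0.30, camera adjusted p = 1.54e-07; adjusted p = 0.609 with an estimated correlation). MRPL58 (-1.35 ± 0.12) and TACO1 (-1.30 ± 0.13) fell. Genes of MYC activity and ribosome biogenesis were higher, 8 of 28, with 1 lower (median 0.23, camera adjusted p = 0.000797; adjusted p = 0.609 with an estimated correlation), with MYC itself at 0.90 ± 0.08. Of 35 lysosome genes, 5 fell and 1 rose (camera adjusted p = 0.00358; adjusted p = 0.609 with an estimated correlation), including HEXA (-0.77 ± 0.09). Adjusted over the list alone, 25 integrated stress response genes were lower and 3 higher, 29 of the mitochondrial ribosome lower and 2 higher, 20 assembly factors lower and 3 higher, 14 genes of MYC activity higher and 2 lower, and 13 lysosome genes lower and 2 higher.

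Between G2 and G1, 1742 genes passed limma's threshold, 873 higher and 869 lower, of which 46 and 81 changed by at least 2-fold, and 18 lists passed camera (5 up, 13 down). With an estimated correlation 0 lists passed, 2 had an unadjusted p under 0.05, and fry called 5. The gene count depended on the arrays kept. Leaving out G1 replicate 3, G2 replicate 1 or G2 replicate 3, which leaves 1 array in a group, removed nearly all calls. PCDH19 then differed by 3.10, 3.10 and 3.17 log2. The arrays of the groups did not overlap for any of the 1742 genes, so leaving out an array could not turn a sign. The count was 1861 without G1 replicate 1, 1220 and 1217 without G0 replicate 1 and without G0 replicate 3, 2663 with dim genes left out and 209 with every row of the table tested by itself.

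Podocyte, renal tubule, fibroblast, immune and endothelial markers did not pass camera in the comparisons with G0. The adjusted p in G1 and G2 was 0.249 and 0.381 for podocyte markers, 0.518 and 0.751 for renal tubule markers, 0.356 and 0.264 for fibroblast markers, 0.716 and 0.795 for immune markers and 0.566 and 0.531 for endothelial markers. Neuronal and adrenal lineage markers passed in G1 (6 of 29 higher, 1 lower, adjusted p = 0.0453; adjusted p = 0.324 with an estimated correlation), including NEFM at 1.21 ± 0.12 log2, and not in G2 (adjusted p = 0.553). Interferon response genes had adjusted p = 0.716 in G1 and 0.696 in G2, and p53 targets 0.629 and 0.239. For p53 targets in G1, renal tubule and endothelial markers in both, interferon genes in G1 and immune markers in both, the median, the mean and the direction of the test did not all have the same sign. In G1, 6 neuronal and adrenal markers rose and 1 fell when adjusted over the list alone.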

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

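The tests of explanations in this part were chosen after the results they bear on had been seen, while the gene list tests, with the preset and the estimated correlation, were planned. Of 22 unnamed rows whose IDs carry M in place of a chromosome number, 10 reached the table's maximum on at least 1 array and 12 did not. For named rows the code equals the chromosome in 99.25% of 22167. These rows entered no gene comparison. Over the 12 below the maximum, the median difference from G0 was 2.05 log2 in G1 (lowest -0.113) and 0.844 in G2 (lowest -0.583). In a separate fit of all 67414 rows, adjusted over those rows, 10 of the 12 passed limma's threshold upward in G1. In G2 6 passed upward, and 0 passed downward in either. Most of these rows were higher in G1 replicate 1 than in G1 replicate 3. In the row with the largest G1 difference from G0 the values were 15.007 and 14.334. In the row with the lowest they were 12.363 and 12.862. The rows need not be independent, so their counts are descriptive. Gene names for the rows with the M code were not used here.

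Nuclear genes for the respiratory chain, ATP synthase and the mitochondrial ribosome, 144 together, had a median of -0.364 in G1 and -0.568 in G2, and the lists they come from did not pass with an estimated correlation (mitochondrial ribosome adjusted p = 0.39 and 0.343). Among 10000 random lists matched on gene span and mean level, the lowest median was -0.206 for G1 and -0.324 for G2, which argues against a trend with span or level as the whole cause. A loss of short abundant transcripts would lower the 46 cytosolic ribosomal protein genes at least as much, and their median was -0.026 in G1 (8 lower, 5 higher) and 0.0478 in G2 (3 lower, 8 higher). Fewer mitochondrial transcripts of every origin would put the rows with the M code below 0, and the median of those below the maximum was 2.05 in G1 and 0.844 in G2. A difference of genotype, of the cell lines apart from genotype, of an unrecorded batch, or of a state that varies within a line stays open: each group is 1 line, and this list also had a median of -0.145 for G1 replicate 1 minus replicate 3.

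The integrated stress response list passed camera as lower in G1 and G2, and not with an estimated correlation (adjusted p = 0.494 and 0.406). Its median of -1.43 in G2 lay below the lowest of 10000 matched random lists, -0.492, and leaving out any 1 array left the median in G1 at -0.5 or lower, so neither a trend with span or level nor a single array accounts for it as a whole. A state that also varies between arrays of 1 line may contribute: the difference between the G1 arrays correlated with G2 minus G0, which does not use them, at r = 0.444 across genes, and 41 of 47 genes of the list were lower in G1 replicate 1 than in replicate 3, with a median of -0.307, while 35 of 39 immediate early genes were higher there (median 0.189). Correlations of this kind were 0.146 for the G0 arrays with G2 minus G1 and -0.056 for the G2 arrays with G1 minus G0. Each uses a different comparison, and they do not show that the G0 arrays were alike on this list. The list's median in G1 against G0 was -1.03 without G0 replicate 1 and -0.5 without G0 replicate 3. In G2 against G0 it was -1.78 and -1.17. Genotype, cell line and batch stay open and were not tested.

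APOL1 held the same value on 5 of 6 arrays. A ceiling is argued against, as APOL1 lay 11.9 log2 below the table's maximum. Median polish can return the same summary for several arrays, and 194 other gene rows below the maximum held exactly equal values on 2 or more arrays. How many of these were tied on as many as 5 arrays was not counted. The tie may come from the summary step, which was not tested further. Whether the lines differ in APOL1 stays open, since no other measure of it was used here.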

How the results depend on the processing

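The alternatives that left out gene rows with ties or removed a trend with gene span and level were chosen after seeing the data. The numbers of genes past the threshold stayed within 1.5 times under the prior variance choices, both scalings, the mean of rows, only the 4 arrays of a comparison and rows with ties left out. Of the genes called, none turned sign under the scalings or the mean of rows. The other choices leave each log2 difference as it is, so no sign could turn under them. The scalings moved the median of all genes by at most 0.0413 log2. Demanding a change of at least 2-fold left 901 genes for G1 against G0, 1862 for G2 against G0, 127 for G2 against G1, 1968 for the F test and 794 changed the same way in both, by construction. Between G2 and G1, leaving out dim genes gave 2663 genes and testing every row by itself gave 209; the cause was not tested. Leaving out 1 array gave 3350 to 4841 genes for G1 against G0, 1 to 1861 for G2 against G1 and 2938 to 4355 changed the same way in both; a lone array is then assumed to vary like the other groups. The labels do not say whether same-numbered arrays shared a culture or a run. Replicate 3 minus replicate 1 correlated over genes at 0.114 for G0 with G1, -0.033 for G0 with G2 and -0.029 for G1 with G2. These values cannot exclude a shared run. With the number as a block the counts were 5250, 7230 and 1587. For gene lists, the estimated correlation left 0 lists in each comparison, and fry called 5 between G2 and G1. The test with an estimated correlation rests on 3 residual degrees of freedom, which by itself raises p. For the NF-kappaB and inflammatory list in G1 the estimated correlation was -0.0103, below the preset 0.01. Its unadjusted camera p was still 0.0151, against 1.11e-05 with the preset. Failing this test therefore does not show that correlation between genes made a list pass. With the trend of span and level removed, 27 lists passed in G1 and 28 in G2. No list reversed.

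Reversals concerned differences near 0 that passed no threshold, and their cause was not tested. Median centring gave 0.006 for APOL3 and 0.0149 for APOL6 in G1 against G0, and 0.0185 for APOL3 and 0.0062 for APOL5 in G2 against G0. Cyclic loess gave -0.0143 for APOL6 in G2 against G0, and -0.0255 for APOL3 and -0.0077 for APOL6 in G2 against G1. Leaving out 1 array gave -0.1462 to 0.0432 for APOL2, -0.0853 to 0.0318 for APOL3 and -0.0944 to 0.0586 for APOL6 in G1 against G0. In G2 against G0 it gave -0.0482 to 0.0025 for APOL3, -0.1049 to 0.0348 for APOL5 and -0.0748 to 0.0782 for APOL6. In G2 against G1 it gave -0.0547 to 0.0625 for APOL3 and -0.0034 to 0.0426 for APOL6. For IGFBP3, a YAP and TAZ target outside the naming rule, in G2 against G1 the range was -0.0959 to 0.0123. Single genes named elsewhere lost the threshold in 718 of their values under the alternatives and gained it in 35. In 6797 they stayed on the same side of it, which includes genes that passed in neither fit. Values near the table's floor or ceiling limit what the arrays can show.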

Other observations

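The camera test of YAP and TAZ targets was chosen before its values were seen; its adjustment over 51 lists and the other values in this part were chosen after seeing the data. The genes given with values in this part lie outside the naming rule for these comparisons and were chosen after their values were seen. Of the 19 genes past the threshold in opposite directions against G0, 13 were lower in G1 and higher in G2, among them HIF1A, the hypoxia-inducible factor (-0.26 in G1, 0.50 in G2), the chromatin factor gene SUPT16H (-0.40, 0.44), RALGAPA1 (-0.38, 0.68) and CD109 (-0.60, 0.48). The other 6 were higher in G1 and lower in G2, among them JAKMIP2 (0.37, -0.84) and ENPP2, which encodes autotaxin (0.35, -0.60). Their difference between G2 and G1 follows from this choice and is no separate test.

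Small nucleolar RNA genes, which guide the modification of ribosomal RNA, were compared as a class. Of 239, 48 were lower and 13 higher in G1 than in G0, while 37 were lower and 33 higher in G2. Between G2 and G1, 16 were higher and 0 lower, with a median of 0.147 log2. Pseudogenes, 936 in all, gave 16 higher and 124 lower in G1 than in G0, 59 higher and 93 lower in G2, and 39 higher and 9 lower between G2 and G1. Neither class was tested against other genes.

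ANKRD1, CCN1 and CCN2 are textbook targets of the transcriptional coactivators YAP and TAZ, which respond to cell density, shape and adhesion. A wider rise of that program was tested on a published signature of 22 genes, all measured, leaving out ANKRD1, CCN1, CCN2 and TGFB2, which had been seen. Among the remaining 18 genes, limma called 8 higher and 1 lower in G1 than in G0, and 10 higher and 0 lower in G2. Their medians were 0.134 in G1 (limma camera adjusted p = 0.00801 over 51 lists, 0.00377 before adjustment) and 0.294 in G2 (adjusted p = 0.000181, 4.26e-05 before adjustment). With an estimated correlation neither passed (adjusted p = 0.375 in G1 and 0.301 in G2). CRIM1 (1.17 in G1, 1.57 in G2), LATS2 (1.09, 1.47) and FOXF2 (0.99, 1.48) were among those that rose, and 1 of the 18 is also in a list fixed earlier. The values with the preset correlation fit a hypothesis of higher YAP and TAZ activity in the risk-variant lines; a difference in cell density or attachment at harvest may give the same picture and was not tested.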
